A study of Homo sapiens with 9 samples.

How the data were processed

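RNA was measured by sequencing in 9 cultures of HBEC-5i, an immortalised human brain microvascular endothelial cell line. Per the labels' protocols, 3 cultures were exposed to live Fusobacterium nucleatum (Fn) and 3 to live Porphyromonas gingivalis (Pg), both Gram-negative anaerobes of dental plaque, at a multiplicity of infection (MOI, bacteria per cell) of 500 for 3 h. The cells were then washed and kept in fresh medium until harvest, at a time not given in the sources used here. The 3 controls had the same washes and medium changes without bacteria. Total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit, per the labels. Nothing in the labels says whether the 3 replicates of a group were separate cultures on separate days. The p-value of a gene thus measures the spread between these samples, which may be partly technical. List p-values also depend on the correlation assumed between genes, as given below.

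Per the submitters' processing notes, Trimmomatic, HISAT2 and StringTie were used with the hg38 build; their versions, their settings and whether counting used strand are not given in the sources used here. The authors deposited a table of estimated counts per gene, whole numbers not scaled to depth, with 67562 rows: 58827 under gene names and 8735 under StringTie's own names (MSTRG) for assembled loci without a gene name. All 9 libraries are at 0 in 19412 of these rows, and no row has a blank or summary name. Low values in this table are more frequent at multiples of about 2.68, rounded up (6, 9, 11 and 14), than at the whole numbers beside them; equally good steps run from 2.67 to 2.7. Values of 1 and 2, below such a step, are the most frequent of all, so treating 2.68 estimated counts as one unit of sequence evidence is an approximation. The detection floor used for bounds is 3 such steps, or 8.04 estimated counts. A second deposited table holds log2 CPM, counts scaled to library size, for 31722 rows. These values were recomputed from the counts of the same rows to within 5.15e-14. The recomputation used edgeR's formula for log2 CPM, written out in numpy, with a prior count of 2 and no library scaling. The rows of the second table are those that edgeR's filter on low counts keeps.

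The estimated counts, already whole, were analysed in edgeR 4.0.16 under R 4.3.3. Rows were kept with filterByExpr and libraries were scaled by TMM. Dispersions were estimated robustly, one mean per group was fitted to all 9 libraries with the quasi-likelihood model (glmQLFit, robust), and each pair of groups was tested two-sided with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 31722 rows tested, of which 24050 have a gene name. The standard error (SE) of a log2 fold change was taken from the same test as its size divided by the square root of F. CPM values are TMM-scaled, and a mean ± SD is over n = 3 libraries, unless stated otherwise. Cell type markers, leukocyte genes and the 5 CPM cut for rows at 0 in other libraries were scaled to library totals without TMM. The floor of a single library was scaled in the same way. The common biological coefficient of variation was 0.605.

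Tests, samples, gene lists, naming rule and most alternatives were fixed before the data were examined. The 39 gene lists comprised 29 pathways or gene families, 6 sets of cell type markers and 4 sets of technical or housekeeping transcripts. Of their members, 1163 were found in the count table, 79 of them through an older symbol, and 22 were not matched. Each list was tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01) on log2 CPM against all other tested rows, adjusted over the lists. Camera at an estimated correlation and fry were run beside it. Among lists that passed in at least 1 comparison, the estimated correlation ran from 0.072 (bacterial sensing) to 0.799 (interferon-stimulated genes). It was 0.654 for cytokines and chemokines. List p-values at the preset thus treat genes that vary together nearly as replicates. A list score in a library is the mean, over members at 1 CPM or more, of log2 CPM minus that gene's mean over the 9 libraries.

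Named genes followed a rule. In each comparison it took the 10 largest rises and falls among genes past the threshold that have a symbol, at least 5 CPM in the higher group and no overlap between replicates. Where fewer than 10 passed, it took the 5 with the smallest unadjusted p per direction, given as values; the symbol, level and overlap criteria were kept for these. It added up to 4 members with the smallest unadjusted p of each list described, and GAPDH, ACTB, TLR2, TLR4, NOD1 and NOD2 as references. Features outside the rule are named as such. A gene that the rule took is not reported here. Coordinates are from GENCODE 29 on GRCh38, which is hg38; 18179 of the 24050 named rows tested have the same symbol there. Without stated strand, reads of overlapping or antisense genes cannot be told apart.

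The pipeline was tested on simulated data with the means, library sizes and dispersions of the real libraries. For Fn vs control, 24 of 100 genes changed 4-fold and 0 of 100 changed 2-fold were called, with 1 false call. For Pg vs control these were 32 of 100, 1 of 100 and 2. For Fn vs Pg they were 25 of 100, 2 of 100 and 0. Gene calls at this spread therefore cover large changes only.

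Totals ranged from 83164104 to 127006442 estimated counts per library, so the floor lies between 0.0633 and 0.0967 CPM in a single library. This floor covers counting error only. No replicate pair was alike within counting error: the chi-square per degree of freedom ran from 96.6 to 194. Alternatives were RLE scaling, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, limma on the deposited log2 CPM, the 6 libraries of a comparison alone, a replicate block, a stricter threshold, a 2-fold minimum, and each library left out. Leaving out the assembled loci and dividing the counts by 2.68 were added after seeing the data. Unchanged groups were simulated 20 times for the comparisons that share the control libraries, and other splits of the libraries were refitted. Both deposited tables and all 9 samples were used. Figures were drawn with matplotlib 3.10.9.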

Results

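Gene expression was measured in 9 RNA libraries of HBEC-5i cells, a line derived from human brain microvessels. There were 3 uninfected control libraries, 3 libraries from cells exposed to F. nucleatum (Fn) and 3 from cells exposed to P. gingivalis (Pg), at an MOI of 500 for 3 h. The design asks how each bacterium alters the transcriptome of these cells, and whether both do so alike. Control libraries held 83164104, 127006442 and 121077925 estimated counts, Fn libraries 116549681, 120762577 and 125985862, and Pg libraries 107042581, 118513500 and 125005927. Assembled loci without a gene name took 21.7% to 24.2% of the counts.

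Taken over the 3 groups together, libraries of one group were no more alike than libraries of different groups. Pairs within a group differed by group, with correlations of log2 CPM of 0.936 to 0.943 in Fn, 0.928 to 0.938 in Pg and 0.899 to 0.915 in controls. Across tested rows, which are not independent replicates, the correlation of log2 CPM had a median of 0.931 over 9 pairs within groups (0.899 to 0.943) and 0.930 over 27 pairs between groups (0.902 to 0.940). The first principal component held 20.7% of the variance and set control 1 apart, and the second held 16.3% and set control 3 apart. The 3 Fn libraries lay close together, and Pg 1 lay nearer to them than to Pg 2 and Pg 3.

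**Figure D1:**
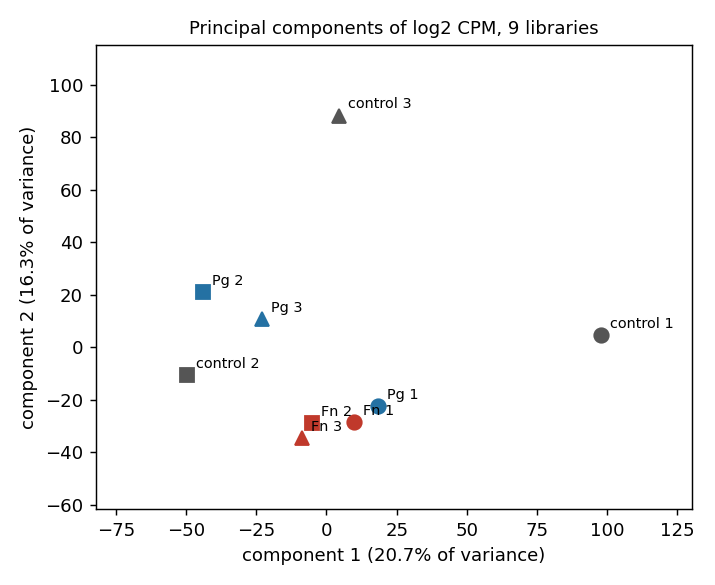
First and second principal components of log2 CPM (arbitrary units), with 20.7% and 16.3% of the variance; each point is 1 library, coloured by group and shaped by replicate. Control 1 and control 3 lie apart from the other libraries, and Pg 1 lies beside the Fn libraries.

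The references included 4 bacterial sensors. TLR4, the lipopolysaccharide receptor, was at 52.99 ± 7.52 CPM in controls, 44.8 ± 8.07 CPM in Fn and 52.7 ± 12.5 CPM in Pg cells (SD, n = 3). NOD1, a sensor of peptidoglycan fragments, was at 9.62 ± 5.01, 8.53 ± 0.679 and 11.02 ± 2.79 CPM. TLR2 (1.33 ± 0.501, 1.16 ± 0.783 and 1.48 ± 2.19 CPM) and NOD2 (0.832 ± 0.0547, 0.723 ± 0.200 and 0.350 ± 0.345 CPM) were low, and each Pg library lay below each control in NOD2 (log2 fold change -1.25, SE 0.63). The glycolytic enzyme gene GAPDH was at 3513 ± 282 CPM in controls, 3276 ± 100.4 CPM in Fn and 3345 ± 306 CPM in Pg cells, and ACTB, which encodes cytoplasmic actin, at 1294 ± 190, 1125 ± 199 and 1175 ± 59.9 CPM. None of these 6 genes passed the threshold in any comparison (edgeR quasi-likelihood test, adjusted p of 0.9999 to 1).

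The comparison of Fn with control asks what F. nucleatum changed. In edgeR fitted to all 9 libraries no named gene passed the threshold, the smallest adjusted p of a named gene being 0.439. Fitted to the 6 Fn and control libraries alone, edgeR called 5 rows higher, 3 of them named genes. DESeq2 called 41 named genes higher and 19 lower. On the rows tested in edgeR, DESeq2 called 160 rows in the real split of these 6 libraries and 84 to 616 in the other splits. Adjusted p below are from edgeR, and DESeq2 called all of the following genes but ALPK2. Among named genes whose replicates did not overlap, OGFRL1 (chromosome 6, 71288803 to 71308950) was at 92.5 ± 9.47 CPM in Fn and 45.9 ± 6.57 CPM in control cells, a log2 fold change of 1.01 (SE 0.17, adjusted p = 0.586). EXT2, a glycosyltransferase of heparan sulfate synthesis (chromosome 11, 44095549 to 44245429), was at 126.5 ± 20.3 against 69.2 ± 3.03 CPM. The centrosomal gene CNTRL had 19.3 ± 7.12 against 6.09 ± 1.77 CPM, the kinase gene NEK4 44.6 ± 5.83 against 16.97 ± 3.15 CPM, and WDR89 7.90 ± 0.855 against 1.97 ± 0.742 CPM. In the other direction, TMEM248, which encodes a transmembrane protein (chromosome 7, 66921225 to 66958551), was at 24.6 ± 6.04 CPM in Fn and 66.7 ± 8.65 CPM in control cells, a log2 fold change of -1.44 (SE 0.21, adjusted p = 0.459). RIOK1, a kinase of small ribosomal subunit maturation, was at 15.2 ± 2.39 against 48.1 ± 5.84 CPM and ALPK2 at 29.2 ± 5.13 against 53.9 ± 10.8 CPM. Of 2 transcripts with clone-based names, CTD-2583A14.10 was at 3.35 ± 0.468 against 8.10 ± 0.376 CPM and RP6-99M1.3 at 0.219 ± 0.036 against 5.91 ± 3.49 CPM.

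In that comparison edgeR called 1 row higher and 0 lower of 31722, and 1280 rows had an unadjusted p under 0.05, where chance gives 1586. Replicates of the 2 groups did not overlap in 9.62% of rows, and chance gives 10%. The called row is an assembled locus, MSTRG.20528, outside the naming rule and named after its values were seen. It had 0 counts in all 3 controls, 9.08 ± 0.241 CPM in Fn and 8.90 ± 0.861 CPM in Pg cells (SD, n = 3; edgeR adjusted p = 9.58e-04 and 9.69e-04). These means are at least 378-fold and at least 370-fold above the floor of the 3 controls pooled, 0.024 CPM. This bound covers counting error only. DESeq2 called 87 rows higher and 54 lower, limma-voom 1 and 0, and limma on the deposited log2 CPM 3 and 1. Without control replicate 2 edgeR called 5 higher, without control replicate 3 it called 2 higher, and without control replicate 1 it called 1 higher and 1 lower.

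**Figure D2:**
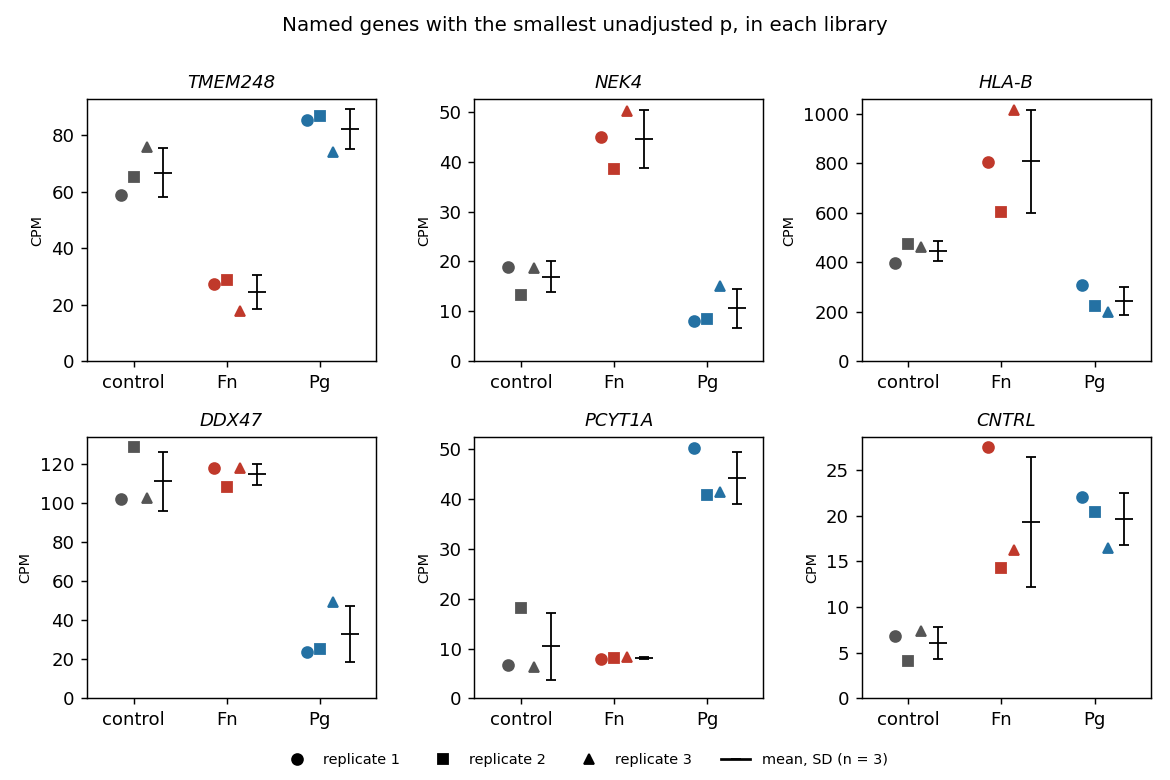
CPM (linear axis from 0) of 6 of the genes that the naming rule took for a small unadjusted p in at least 1 comparison. The rule kept named genes at 5 CPM or more in the higher group without overlap between replicates. Symbols are replicates and the bar is the mean with its SD (n = 3). TMEM248 lies at 24.6 ± 6.04 CPM in Fn cells, below the other groups, and DDX47 at 33.0 ± 14.4 CPM in Pg cells, below the other groups.

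By gene list, 6 of 39 lists passed in Fn against control (camera, preset correlation), 5 towards higher and 1 towards lower values; 3 passed without control replicate 3 and 10 without control replicate 2. With an estimated correlation no list passed. Among interferon-stimulated genes, 39 of 41 had a positive log2 fold change, with a median of 0.67 (adjusted p = 3.88e-09; adjusted p = 0.807 with an estimated correlation). The members with the smallest p were ISG20, an RNA exonuclease gene (94.6 ± 22.3 CPM in Fn, 37.4 ± 12.4 CPM in control cells), OASL (403 ± 53.8 against 216 ± 88.4 CPM), CMPK2 (196.7 ± 35.3 against 67.6 ± 40.1 CPM) and IFIT2 (926 ± 161.6 against 460 ± 225 CPM). Of the cytokine and chemokine genes, 25 of 29 were positive, with a median of 0.50 (adjusted p = 1.52e-06; adjusted p = 0.807 with an estimated correlation). CXCL10, a T cell attracting chemokine, was at 64.2 ± 23.8 against 10.5 ± 5.91 CPM, a log2 fold change of 2.61 (SE 0.75), CXCL11 at 71.4 ± 16.4 against 16.3 ± 7.37 CPM, the monocyte chemokine CCL2 at 268 ± 24.4 against 83.4 ± 52.9 CPM, and CCL5 at 51.8 ± 6.67 against 30.5 ± 12.7 CPM. All 4 chemokines were higher in each Fn than in each control library, CCL5 narrowly so. They were taken as the members with the smallest p, and 6 of the 29 members were higher in this way. The list score of control 1 (0.97) lay above those of Fn 2 (0.66) and Fn 3 (0.69).

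Among NF-kB targets 22 of 25 were positive in Fn against control (median 0.33, adjusted p = 4.43e-04), with NFKB2 at 33.2 ± 4.76 against 16.7 ± 0.971 CPM, BIRC3 at 91.5 ± 12.9 against 58.2 ± 16.1 CPM, NFKBIA at 181 ± 2.58 against 144 ± 25.9 CPM and IL32 at 14.7 ± 4.13 against 8.58 ± 4.49 CPM. Of the cholesterol synthesis and SREBP2 target genes 22 of 25 were positive (median 0.24, adjusted p = 0.00138). INSIG1, a regulator of sterol synthesis, was at 64.1 ± 7.01 against 44.6 ± 12.7 CPM, LSS at 81.5 ± 2.96 against 67.4 ± 5.52 CPM and DHCR7 at 26.0 ± 0.811 against 19.2 ± 3.26 CPM. The unfolded protein response chaperones had 21 of 26 positive members (median 0.21, adjusted p = 0.00434), DNAJB9 (26.8 ± 3.61 against 18.1 ± 3.87 CPM) and SDF2L1 (13.6 ± 0.750 against 10.2 ± 1.21 CPM) among them, while HYOU1 was at 34.3 ± 8.01 against 52.5 ± 4.91 CPM. Ribosomal protein genes had 68 of 75 negative members (median -0.13, adjusted p = 4.43e-04), such as RPL34 at 265.6 ± 15.3 against 381 ± 77.6 CPM and RPS29 at 238 ± 28.3 against 313 ± 46.1 CPM. In edgeR no member of the 6 lists was called, over all genes or adjusted over the list alone; DESeq2 called CXCL10 (adjusted p = 0.0444). With an estimated correlation the adjusted p was 0.807 for the first 3 of these lists and 0.877 for the ribosomal genes.

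Single libraries decided several of these calls and moved the medians (camera, preset correlation). Without control replicate 3 the median was 0.35 for interferon-stimulated genes, 0.19 for cytokines and chemokines, 0.20 for NF-kB targets (adjusted p = 0.117), 0.13 for the cholesterol list (adjusted p = 0.154), 0.13 for the chaperones (adjusted p = 0.303) and -0.10 for ribosomal protein genes (adjusted p = 0.117). Leaving out control replicate 1 gave medians of 1.97 for cytokines and chemokines, 0.51 for NF-kB targets, -0.22 for ribosomal protein genes, 0.13 for the cholesterol list (adjusted p = 0.128) and 0.15 for the chaperones (adjusted p = 0.109). Leaving out control replicate 2 gave 1.16 for interferon-stimulated genes, 0.32 for cytokines and chemokines, 0.48 for the cholesterol list, 0.35 for the chaperones and -0.03 for ribosomal protein genes (adjusted p = 0.451). Without Fn replicate 1 the cytokine and chemokine median was 0.30 and the ribosomal genes had an adjusted p of 0.0997, and without Fn replicate 3 the cholesterol median was 0.15 (adjusted p = 0.0607). At this preset correlation the interferon-stimulated and cytokine lists stayed under 0.05 with each Fn or control library left out in turn. Leaving out a library keeps the preset, so this does not test it. With an estimated correlation both lists had an adjusted p of 0.807 over all libraries.

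**Figure D3:**
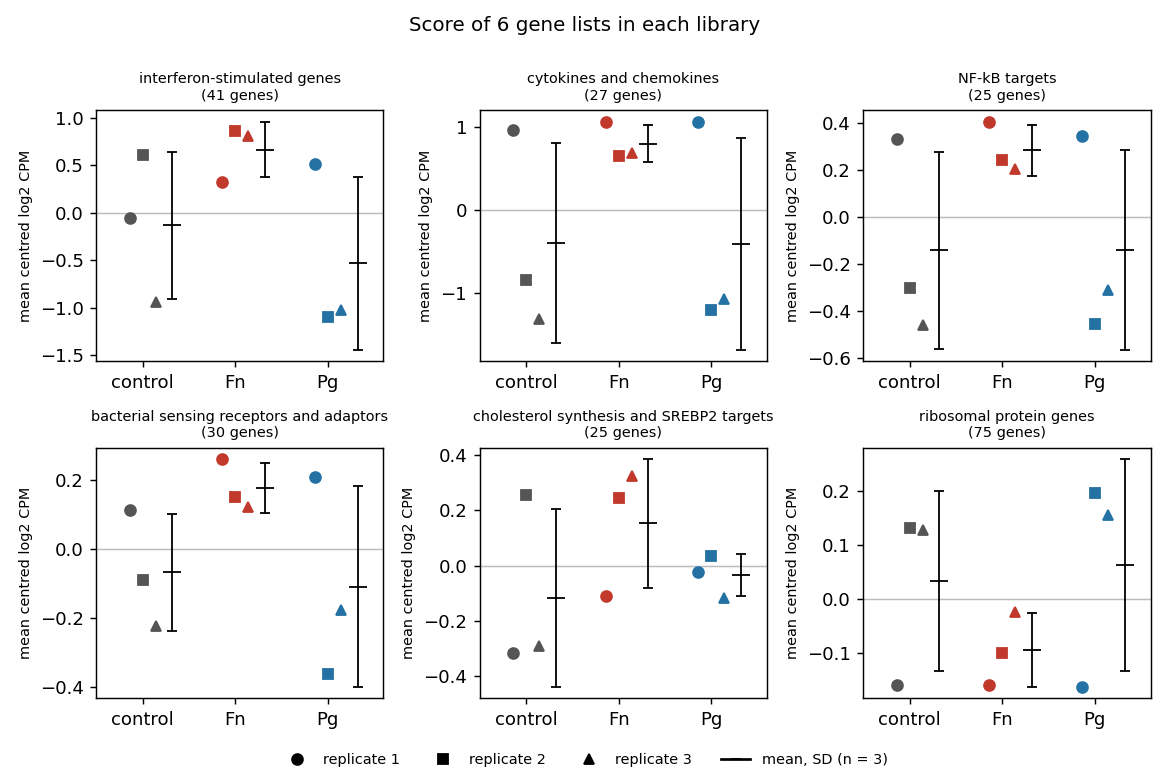
Score of 6 gene lists (mean centred log2 CPM of members at 1 CPM or more, linear axis) in each library; symbols are replicates and the bar is the mean with its SD (n = 3). The cytokine and chemokine score is 0.97 in control 1 and 1.06 in Pg 1, within the range of the Fn libraries or above it, and below -0.8 in the other control and Pg libraries.

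The comparison of Pg with control asks what P. gingivalis changed. In edgeR no named gene passed the threshold, the smallest adjusted p of a named gene being 0.291, while DESeq2 called 34 named genes higher and 28 lower. On the rows tested in edgeR, DESeq2 called 157 rows in the real split of these 6 libraries and 138 to 2130 in the other splits. It called all of the following genes but RNF14, and the adjusted p given are from edgeR. CYLD, a deubiquitinase gene that restrains NF-kB signalling (chromosome 16, 50742050 to 50801935), was at 38.6 ± 13.5 CPM in Pg and 15.2 ± 1.70 CPM in control cells, a log2 fold change of 1.34 (SE 0.25, adjusted p = 1). PCYT1A, which encodes the rate-limiting enzyme of phosphatidylcholine synthesis (chromosome 3, 196214222 to 196287957), was at 44.2 ± 5.22 against 10.4 ± 6.73 CPM, CNTRL at 19.6 ± 2.83 against 6.09 ± 1.77 CPM, the mRNA decay gene RC3H2 at 61.9 ± 4.48 against 30.9 ± 4.58 CPM and the ubiquitin ligase gene RNF14 at 69.5 ± 16.7 against 37.1 ± 5.28 CPM. The RNA helicase gene DDX47 (chromosome 12, 12813316 to 12829981) was at 33.0 ± 14.4 CPM in Pg and 111 ± 15.1 CPM in control cells, a log2 fold change of -1.75 (SE 0.28, adjusted p = 0.683). A second helicase gene, DDX1, was at 33.8 ± 10.8 against 103.8 ± 37.0 CPM, the splicing gene PNN at 64.7 ± 5.97 against 126 ± 22.04 CPM, RNF149 at 18.6 ± 6.76 against 62.2 ± 6.995 CPM and the DNA repair nuclease gene FAN1 at 6.65 ± 3.18 against 21.5 ± 5.72 CPM.

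For Pg against control edgeR called 1 row higher, the assembled locus MSTRG.20528, and 0 lower, with 1124 rows at an unadjusted p under 0.05 against 1586 by chance. Replicates did not overlap in 7.07% of rows, with 10% given by chance. DESeq2 called 85 rows higher and 64 lower, limma-voom 2 and 0, and limma on the deposited log2 CPM 4 and 1. In edgeR, leaving out control replicate 2 gave 5 higher and 1 lower, with PCYT1A among them (adjusted p = 0.00891). Leaving out Pg replicate 3 gave 3 higher and 2 lower, with DDX47 among them (adjusted p = 0.0204), and leaving out control replicate 3 gave 2 higher. Fitted to its 6 libraries alone, this comparison gave 0 calls.

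Of the gene lists, 1 of 39 passed in Pg against control; the number was 0 without Pg replicate 2, 2 without Pg replicate 3, 7 without Pg replicate 1, 3 without control replicate 1 and 4 without control replicate 2. The interferon-stimulated genes had a negative log2 fold change in 38 of 41 members, with a median of -0.36 (camera, preset correlation, adjusted p = 0.0169; adjusted p = 0.983 with an estimated correlation). Members with the smallest p were XAF1 (40.7 ± 25.0 CPM in Pg, 100.2 ± 77.7 CPM in control cells), IFI44 (30.2 ± 8.51 against 51.2 ± 28.1 CPM), IFI27 (94.8 ± 79.5 against 166.5 ± 61.9 CPM) and RSAD2 (113 ± 120.4 against 51.1 ± 46.9 CPM), the last in the opposite direction. In edgeR no member was called over all genes or adjusted over the list alone. The direction rested on single libraries: the median was 0.14 without control replicate 2 and -1.07 without Pg replicate 1. The adjusted p was 0.819 without control replicate 2, 0.803 without Pg replicate 2 and 0.668 without Pg replicate 3, with medians of -0.11 in the last 2 cases, and the median was -0.66 without control replicate 3. The cytokine and chemokine list had a median of -0.14 (adjusted p = 0.862) and NF-kB targets one of -0.03 (adjusted p = 0.962).

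**Figure D4:**
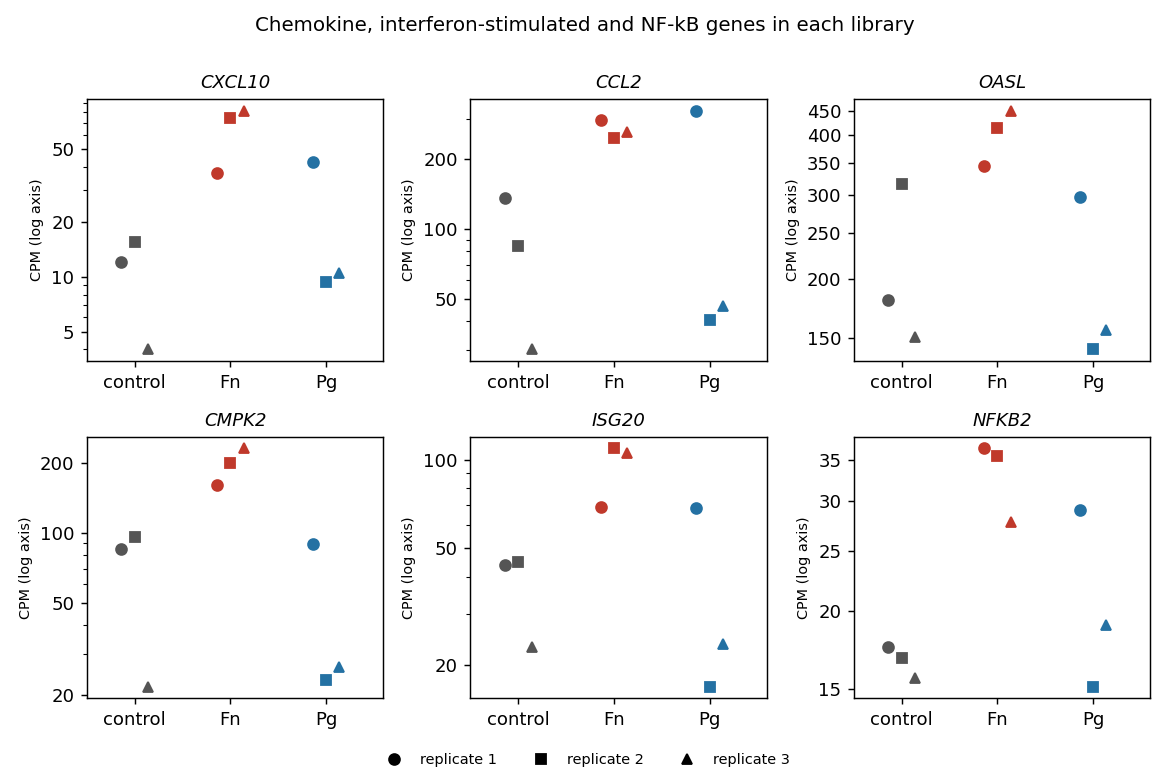
CPM (log axis) of 6 chemokine, interferon-stimulated and NF-kB genes in each library, coloured by group and shaped by replicate. CXCL10 lies between 37.0 and 81.1 CPM in Fn cells and at 42.9 CPM in Pg 1, against 9.34 and 10.5 CPM in Pg 2 and Pg 3 and 4.01 to 15.6 CPM in controls.

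The direct comparison of Fn with Pg asks where the 2 bacteria differ. No row passed in edgeR, and the smallest adjusted p of a named gene was 0.303. On the rows tested in edgeR, DESeq2 called 102 rows in the real split of these 6 libraries and 69 to 141 in the other splits. In its own run DESeq2 called 23 named genes higher and 19 lower, including the 10 that follow. HLA-B, an antigen-presenting class I gene (chromosome 6, 31269491 to 31357188), was at 809 ± 208 CPM in Fn and 243 ± 56.3 CPM in Pg cells, a log2 fold change of 1.73 (SE 0.23, adjusted p = 0.303); its reads can be shared with other class I genes. NEK4 (chromosome 3, 52708449 to 52770949) was at 44.6 ± 5.83 against 10.6 ± 3.96 CPM, a log2 fold change of 2.07 (SE 0.29, adjusted p = 0.303), DDX47 at 114.8 ± 5.56 against 33.0 ± 14.4 CPM, SUCO at 121.7 ± 6.09 against 62.1 ± 6.99 CPM and RNF149 at 49.1 ± 17.1 against 18.6 ± 6.76 CPM. TMEM248 was at 24.6 ± 6.04 against 82.2 ± 7.05 CPM, a log2 fold change of -1.74 (SE 0.21, adjusted p = 0.303). RC3H2 was at 21.5 ± 6.22 against 61.9 ± 4.48 CPM, PCYT1A at 8.14 ± 0.215 against 44.2 ± 5.22 CPM, CNOT6, a deadenylase gene, at 8.39 ± 3.76 against 33.2 ± 5.78 CPM and CCDC186 at 15.4 ± 2.54 against 28.9 ± 0.905 CPM.

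In that comparison 1012 rows had an unadjusted p under 0.05 in edgeR against 1586 by chance, and replicates did not overlap in 10.6% of rows against 10% by chance. DESeq2 called 53 rows higher and 52 lower, limma-voom 0 and 0, and limma on the deposited log2 CPM 1 and 1. In edgeR, leaving out Pg replicate 3 gave 2 higher, DDX47 among them (adjusted p = 0.0445), leaving out Pg replicate 1 gave 1 higher, and the 6 libraries alone gave 1 higher and 1 lower, the latter PCYT1A (adjusted p = 0.0410).

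By list, 9 of 39 passed between Fn and Pg (camera, preset correlation), 6 towards Fn and 3 towards Pg; 5 passed without Pg replicate 2 and 6 without Fn replicate 2. Interferon-stimulated genes were positive in 39 of 41 members, with a median of 1.02 (adjusted p = 8.41e-21), including CMPK2 at 196.7 ± 35.3 against 46.3 ± 37.2 CPM, the interferon signalling gene IRF9 at 49.5 ± 5.02 against 27.2 ± 11.6 CPM, OASL at 403 ± 53.8 against 198 ± 85.6 CPM and ISG20 at 94.6 ± 22.3 against 36.4 ± 28.0 CPM. All 29 cytokine and chemokine genes were positive, with a median of 0.69 (adjusted p = 2.10e-08), such as CXCL10 at 64.2 ± 23.8 against 20.9 ± 19.0 CPM, CXCL11 at 71.4 ± 16.4 against 26.5 ± 26.9 CPM, TNFSF10 at 33.7 ± 10.5 against 12.2 ± 7.67 CPM and CXCL16 at 2.29 ± 0.365 against 1.43 ± 0.384 CPM. NF-kB targets were positive in 23 of 25 (median 0.37, adjusted p = 5.50e-05), with NFKB2 at 33.2 ± 4.76 against 21.1 ± 7.21 CPM and BIRC3 at 91.5 ± 12.9 against 57.1 ± 20.1 CPM. The list of bacterial sensing receptors and adaptors was positive in 19 of 32 members (median 0.19, adjusted p = 0.0499). None of these members had an unadjusted p under 0.05 in edgeR. RIPK2 was at 53.4 ± 4.90 against 41.1 ± 9.06 CPM and CASP1 at 35.6 ± 2.48 against 19.1 ± 13.96 CPM. With an estimated correlation the adjusted p of these 4 lists was 0.700.

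A further 5 lists, of metabolism and growth, passed between Fn and Pg with the preset correlation only. With an estimated correlation the adjusted p was 0.758 for oxidative phosphorylation and 0.700 for the other 4. The ATF4 amino acid response was positive in 30 of 35 members (median 0.16, adjusted p = 1.64e-04), with the tryptophanyl-tRNA synthetase gene WARS at 193.9 ± 51.9 against 111.7 ± 17.6 CPM, SLC3A2 at 181 ± 18.7 against 137 ± 15.1 CPM, TRIB3 at 32.2 ± 3.34 against 24.0 ± 3.02 CPM and DDIT4 at 109 ± 7.86 against 84.8 ± 16.01 CPM. Cholesterol genes were positive in 22 of 25 (median 0.14, adjusted p = 0.0187), LSS at 81.5 ± 2.96 against 64.5 ± 3.70 CPM and DHCR7 at 26.0 ± 0.811 against 19.6 ± 2.82 CPM among them. Ribosomal protein genes were negative in 71 of 75 (median -0.18, adjusted p = 2.88e-06), for example RPL34 at 265.6 ± 15.3 against 351 ± 49.0 CPM and RPL11 at 558.5 ± 24.1 against 707 ± 118 CPM. Mitosis genes were negative in 35 of 40 (median -0.21, adjusted p = 0.00175), with CENPF at 335 ± 26.2 against 499 ± 147 CPM, ASPM at 391.6 ± 14.6 against 547 ± 121 CPM, TOP2A at 840.5 ± 28.6 against 1095 ± 187 CPM and KIF23 at 32.0 ± 13.9 against 59.4 ± 27.9 CPM. Nuclear genes of oxidative phosphorylation were negative in 61 of 73 (median -0.10, adjusted p = 0.0105), with UQCRB at 151 ± 7.53 against 198 ± 42.0 CPM, while NDUFB6 was at 36.7 ± 9.55 against 19.8 ± 7.37 CPM. In edgeR no member of the 9 lists was called, over all genes or adjusted over the list alone.

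The Fn against Pg lists also moved with single libraries. Without Pg replicate 1 the median was 1.68 for interferon-stimulated genes, 1.99 for cytokines and chemokines, -0.30 for ribosomal genes and -0.19 for oxidative phosphorylation, and the cholesterol list had an adjusted p of 0.0894. Without Pg replicate 2 the median was 0.41 for cytokines and chemokines, -0.12 for mitosis genes and 0.13 for bacterial sensing (adjusted p = 0.101 for each of the last 2), -0.10 for ribosomal genes (adjusted p = 0.0926) and -0.03 for oxidative phosphorylation (adjusted p = 0.733). Leaving out Pg replicate 3 gave an adjusted p of 0.209 for bacterial sensing (median 0.12), 0.154 for the cholesterol list and 0.263 for oxidative phosphorylation, and a cytokine and chemokine median of 0.40. Leaving out Fn replicate 1 gave an adjusted p of 0.0884 for bacterial sensing and 0.172 for oxidative phosphorylation and a cytokine and chemokine median of 0.43. Fn replicate 2 (adjusted p = 0.107, 0.117 and 0.0943 without it for bacterial sensing, cholesterol and oxidative phosphorylation) and Fn replicate 3 (adjusted p = 0.117 and 0.219 without it for bacterial sensing and cholesterol) each decided calls as well. The interferon-stimulated, cytokine, NF-kB and ATF4 lists stayed under 0.05 with each Fn or Pg library left out in turn at the preset correlation. This does not test the preset itself. With an estimated correlation these lists had an adjusted p of 0.700 over all libraries.

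**Figure D5:**
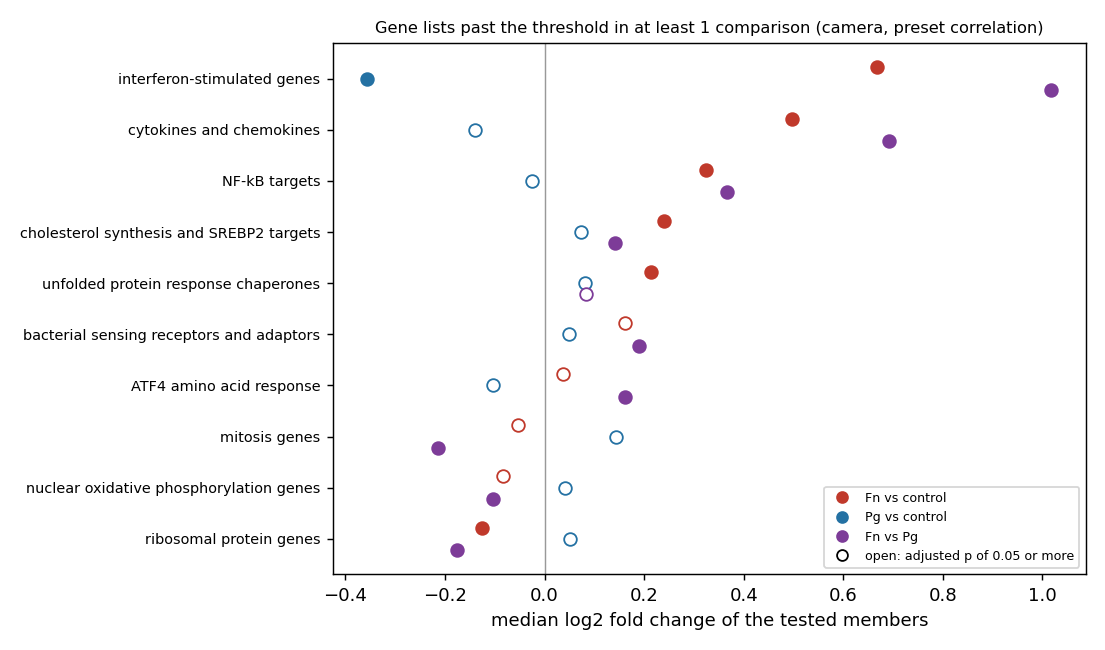
Median log2 fold change of tested members (linear axis) of the 10 lists that passed in at least 1 comparison; colours are comparisons, and filled points passed with camera at the preset correlation. Interferon-stimulated genes have medians of 0.67 in Fn against control, -0.36 in Pg against control and 1.02 in Fn against Pg.

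Whether both bacteria changed the same genes was asked through the 2 comparisons with control. In edgeR they shared 1 call in the same direction, the locus MSTRG.20528, which is at 0 in the controls that both use, and in DESeq2 they shared 54, a number not simulated or set against drawn assignments. The edgeR number was 4 without control replicate 2, 3 without Pg replicate 3 and 2 without control replicate 3. In edgeR simulated unchanged groups shared 0, and 33 of 100 drawn assignments of the libraries to groups, the real one included, shared at least 1. Across tested rows, which are not replicates, the log2 fold changes of both comparisons had a Pearson correlation of 0.61, and 0.50 (0.47 to 0.52 over 20 simulations) in simulated unchanged groups against common controls. In the simulations each row was drawn independently, with the same dispersion in all groups. Their ranges therefore leave out rows that move together and set no chance level. Over the drawn assignments other than the real one the correlation spanned 0.33 to 0.66. The covariance was 0.67 against a simulated 0.41 (0.37 to 0.45), and 0.46 against 0.29 (0.27 to 0.31) among named genes. In 12 of the 100 drawn assignments the covariance was at least 0.67, with a median of 0.50 and a maximum of 0.79 over the assignments other than the real one. With 3 control libraries the controls could not be divided into 2 sets of at least 2 libraries. Part of the excess over the simulations may thus come from the shared controls. Leaving out single libraries moved the correlation between 0.49 (Pg replicate 1) and 0.74 (control replicate 2).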

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

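Of the alternatives, leaving out the assembled loci and dividing the counts by 2.68 were chosen after seeing the data. The main counts were 1 higher and 0 lower in Fn vs control, 1 and 0 in Pg vs control, and 0 and 0 in Fn vs Pg. They stayed there with RLE scaling, the stricter filter, the divided counts, an adjusted p under 0.01 and a 2-fold minimum. DESeq2 called far more: 87 higher and 54 lower in Fn vs control, 85 and 64 in Pg vs control, 53 and 52 in Fn vs Pg, and 54 in both comparisons with control in the same direction. It gave no adjusted p for 10859, 11796 and 9929 rows. Limma on the deposited log2 CPM called 3 and 1, 4 and 1, and 1 and 1, limma-voom 2 higher in Pg vs control, and no low count filter gave 2 higher in each comparison with control. The 6 libraries alone gave 5 higher in Fn vs control, 3 of them named genes, 0 in Pg vs control, and 1 higher and 1 lower in Fn vs Pg. Without the assembled loci there were 0 higher in both comparisons with control and 0 shared, since the called locus was then not tested. The cause of the other changes was not tested.

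The replicate numbers do not pair the samples by the rule set for this, a correlation above 0.1 in every pair: deviations from the group means of same-numbered libraries correlated between -0.038 and 0.181, above 0.1 in 2 of 9 pairs, and 5 of 9 libraries matched best to one with their own number. Some lists did follow the number: the cytokine and chemokine score was highest in replicate 1 of each group (0.97, 1.06 and 1.06 in control, Fn and Pg). Replicate 1 was also highest in each group for NF-kB targets (0.33, 0.40 and 0.34) and bacterial sensing (0.11, 0.26 and 0.21). It was lowest for ribosomal protein genes (-0.16 in each group) and oxidative phosphorylation (-0.15, -0.12 and -0.12). The interferon, cholesterol, ATF4, mitosis and chaperone scores did not follow the number in this way. A batch shared by replicates of 1 number is thus not excluded. With the replicate number as a block there were 0 higher in both comparisons with control and 0 shared, and 6, 1 and 9 lists, with a cytokine and chemokine median of 1.20 instead of 0.50 in Fn vs control and 1.09 instead of 0.69 in Fn vs Pg. The bacterial sensing list in Fn vs Pg had an adjusted p of 0.0589 with the block, and 0.0514 without the assembled loci.

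Lists past the threshold numbered 6, 1 and 9, and 0, 0 and 0 both with an estimated correlation and with fry. The stricter filter gave 9, 2 and 10. Leaving out single libraries gave 3 to 10 lists in Fn vs control, 0 to 7 in Pg vs control and 5 to 11 in Fn vs Pg. Likewise the calls ran from 1 to 5 higher and 0 to 1 lower in Fn vs control, 1 to 5 higher and 0 to 2 lower in Pg vs control and 0 to 2 higher in Fn vs Pg, the shared calls from 1 to 4, and the correlation of fold changes from 0.49 to 0.74. The list that reversed was the interferon-stimulated genes in Pg vs control, from -1.07 to 0.14. Values near 0 also changed sign: GAPDH from -0.129 to 0.008 in Pg vs control and from -0.104 to 0.021 in Fn vs Pg, and TLR4 in Pg vs control from -0.13 to 0.18, and 0.002 with no low count filter. RSAD2 in Pg vs control ran from -0.23 without Pg replicate 1 to 2.2 without control replicate 3. Among values of single genes under all alternatives, 1367 kept their direction and side of the threshold and 8 reversed. Another 33 kept their direction and passed, 29 of them in DESeq2. None of these genes was called in the main fit, so keeping the side meant staying uncalled and says little about stability. Depth limits the values near the floor, which is below 0.1 CPM in each library; recovery at other depths was not tested.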

Other observations

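Markers of cell types, fixed before the data were examined, described the cultures without regard to infection. Of 25 endothelial markers 12 reached 1 CPM over the 9 libraries, with a median of 0.843 CPM. ECSCR (62.2 ± 19.2 CPM, SD, n = 9), EGFL7 (41.4 ± 7.46 CPM), FLI1 (38.8 ± 3.24 CPM), KDR (28.6 ± 17.4 CPM), TEK (23.7 ± 5.06 CPM) and ENG (21.9 ± 8.28 CPM) were the highest. The junction and lineage genes PECAM1 (1.85 ± 0.542 CPM), CLDN5 (0.839 ± 0.389 CPM), CDH5 (0.378 ± 0.298 CPM) and VWF (0.274 ± 0.134 CPM) were low in every library. Fibroblast markers had a median of 31.03 CPM, with COL3A1 at 1046 ± 226 CPM, COL1A2 at 830 ± 286 CPM and COL1A1 at 143.5 ± 31.2 CPM, and pericyte and smooth muscle markers one of 7.26 CPM, with ANPEP at 227 ± 110 CPM and CSPG4 at 88.6 ± 29.2 CPM. Epithelial (0.675 CPM), leukocyte (0.145 CPM) and astrocyte (0.117 CPM) markers had medians under 1 CPM. None of the 6 marker lists passed in any comparison (camera, adjusted p of 0.263 or more).

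In the following weighing, the test of infection as an explanation and that of depth on the cytokine and chemokine score were chosen only after the scores were seen. Interferon and chemokine genes varied widely between libraries of one group: the interferon list score was -0.06, 0.60 and -0.94 in the controls, 0.33, 0.86 and 0.81 in Fn and 0.52, -1.09 and -1.02 in Pg libraries, and the cytokine and chemokine score 0.97, -0.84 and -1.31, then 1.06, 0.66 and 0.69, then 1.06, -1.20 and -1.07. Against infection as the whole explanation, the uninfected controls spanned 1.54, more than the 0.80 between the Fn and control means; RNA of leukocytes is argued against by a median of PTPRC, TYROBP, FCER1G and LYZ of at most 0.227 CPM in a library, and library depth, for the interferon score alone, by a Spearman rho of 0.233 with the total count (exact permutation p = 0.552; Pearson r -0.006, exact permutation p = 0.991, and 0.234 without the 2 totals farthest from the median). For the cytokine and chemokine score depth stays open, with a Spearman rho of -0.533 (exact permutation p = 0.148) and a Pearson r of -0.505 (exact permutation p = 0.142), which is -0.227 without those 2 libraries. This score, unlike the interferon score, was highest in replicate 1 of each group, which also had the lowest total count of its group. Depth and something shared by libraries of 1 replicate number were not told apart. It stays open that 1 library of the Pg group is an F. nucleatum library: of 338 genes outside the immune lists that separate Fn from the other Pg libraries, 76.6% put that library nearer to Fn, and on genes chosen with 2 Fn libraries it had 63.4%, 69.5% and 73.2% where the left-out Fn library had 63.7%, 67.2% and 70.1%. The 3 controls had 64.2%, 53.6% and 31.4% of the 338 genes, so a difference between cultures may raise the share as well, and an effect of F. nucleatum added to that variation was not separately tested.

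Assembled loci read in the 6 infected libraries and at 0 in the 3 controls, such as the called one, could come from an assignment of reads to assembled loci that differed between libraries without regard to group. With 0 counts in 3 libraries and at least 5 CPM in each of the other 6, the controls gave 2 such rows, and 1 of the other 83 choices of 3 libraries also gave 2, their median being 0. Among rows reaching 5 CPM, 12.6% of 5587 assembled loci and 0.338% of 11228 named genes were at 0 in another library. The assignment of reads thus remains a candidate explanation, and with the real split tied for the highest, a transcript induced by infection is not excluded.

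Other splits of the libraries bear on the counts of calls. Each comparison has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 1 gene in Fn vs control, with 3 as the highest of the others (7 of 10 splits gave as many), 1 gene in Pg vs control, with 10 as the highest (5 of 10), and 0 in Fn vs Pg, with 4 as the highest (10 of 10). For gene lists the real splits gave 6, 1 and 9, and the highest others 11, 14 and 11 (7, 10 and 4 of the 10 splits gave as many). For DESeq2 on the 31722 rows tested in edgeR they were 160, 157 and 102, and the highest others 616, 2130 and 141 (3, 9 and 6 of 10). The split with 2130 set Pg 1, control 1 and control 3 against Pg 2, Pg 3 and control 2, and edgeR called 6 genes in it. It was singled out as the largest DESeq2 count after the counts were seen. Whether the samples hold a structure other than infection was not tested. Over 100 drawn assignments of the 9 libraries to 3 groups, the real one included, 33 gave at least the 1 shared call of both comparisons with control (highest other 4), and 8 gave a correlation of fold changes of at least 0.61 (highest other 0.66), so chance cannot be excluded for either.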
